A study of Homo sapiens with 6 samples.

How the data were processed

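RNA-seq was run on total RNA from 3 wild-type and 3 lncBCAS1-4_1-overexpressing samples of H1299 cells. The authors extracted RNA with TRIzol, trimmed reads with fastp, aligned them to GRCh38 with HISAT2, assembled transcripts with StringTie, merged the assemblies with gffcompare and took expression from StringTie, per the labels' protocols. They tested differences with edgeR and called genes at more than 2-fold or less than 0.5-fold with p under 0.05, per the labels. Tool versions, the library kit, its strandedness and the way in which gene counts were taken are not given in the sources used here. The deposited values were raw counts per gene, whole numbers with no normalization, in 1 table of 19201 entries with an Ensembl ID and a symbol each. Every entry analysed here had at least 10 counts in at least 3 libraries, with a lowest total of 31. An Ensembl ID stood in place of a symbol in 2559 entries and 126 shared a symbol with another. No column was left unassigned to a sample.

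Samples were grouped by their labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test after TMM scaling and filterByExpr (min.count 10, min.total.count 15), which left 19101 entries. The model held the group alone, p-values were adjusted by Benjamini-Hochberg over all entries tested, and the threshold was an adjusted p of 0.05. Levels are CPM by TMM-scaled library size, and the SE of a log2 fold change was the fold change divided by the square root of F. Total counts of 84531039 to 92780032 per library mean that low genes, at well under 1 CPM, rest on few counts. Simulated data with known changes in 200 of 19101 genes were used to test the model. The changes were placed in genes with a mean log2 CPM above 2. Without a GC trend, unlike the real data, 61% of 1.5-fold and 97% of 2-fold changes were recovered with 15 false calls. With a GC and length trend added, false calls rose to 5725, and the corrected fit left 19 with 62% and 96% recovered. The added trend was the same in every overexpressing library and of a form that the correction can fit. How the correction does on other trends was therefore not tested.

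A total of 26 gene lists were fixed before the data were examined: glycolysis, mesenchymal, epithelial and vitamin D genes as core lists, 18 lists for other pathways and complexes, and 4 lists of markers of other cell types. Lists were tested with camera of limma 3.58.1 on log2 CPM at its preset inter-gene correlation of 0.01, adjusted over the 26 lists, with an estimated correlation and fry beside it. The genes named in the text were set by a rule fixed at the same time: CYP24A1, VDR and any entry with BCAS1 in its name, the 10 largest rises and falls among genes past the threshold with a symbol, a mean log2 CPM of at least 2 and no overlap between the groups, up to 3 rising and 3 falling members with the smallest p of each core list, up to 2 of each other list, and 10 fixed genes of glycolysis and epithelial-mesenchymal transition. One gene that the rule names is not reported here. Other list members and the genes of the closing families were named after their values were seen.

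Ensembl IDs were looked up in GENCODE 44 (GRCh38), where 19067 matched and 134 did not. Symbols were the same in 18956 entries and differed in 103 others by naming only, such as newer symbols or an ID in place of a name. In 8 further entries the symbol belongs to another Ensembl gene than the ID. The plan had been to match lists by symbol, and this was changed after seeing the data: because neither name could be settled, the 8 entries stayed among the entries tested but in no list, and both readings were run as alternatives. They are named in the text by both symbol and ID.

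GC content and length were those of the GENCODE canonical transcript, known for 99.3% of the tested entries. The correction, also added after seeing the data, fitted natural splines with 5 degrees of freedom of each library's deviation in log2 CPM on GC content and log2 length, and entered them as offsets in the same edgeR fit. Other settings tried, fixed before the data were examined, were DESeq2 size factors (DESeq2 1.42.0) and library size alone in place of TMM, other filters on low counts, DESeq2 and limma-voom in place of edgeR, a block on the replicate number, leaving out each library, an estimated correlation and fry for the lists, and a 2-fold filter. Libraries of a group differed by more than counting noise (chi-square per degree of freedom from 11.6 to 22.7), so none was treated as the same library deposited again; separate preparations of 1 sample would differ in this way too.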

Results

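Gene counts were analysed from 6 RNA-seq libraries of H1299, an established human non-small cell lung cancer line: 3 wild-type control libraries and 3 libraries of cells overexpressing the long non-coding RNA lncBCAS1-4_1. The labels call the controls wild-type and name no vector for them. An effect of the overexpression procedure itself therefore cannot be told apart from an effect of the RNA. This holds for the interferon-stimulated genes below as for every other difference. Total counts were 87393887, 92780032 and 88734459 in controls 1 to 3 and 87563526, 84531039 and 90102655 in overexpressing libraries 1 to 3. No label says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series title places the RNA beside CYP24A1, active vitamin D, glycolysis and epithelial-mesenchymal transition, and the comparison asks how the transcriptome of H1299 differs with its overexpression.

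CYP24A1, the mitochondrial hydroxylase that inactivates 1,25-dihydroxyvitamin D, showed the largest rise among the genes named here. Its level was 0.778 ± 0.158 CPM (counts per 1e6 library counts; SD, n = 3) in the controls and 2908 ± 591 CPM (SD, n = 3) in the overexpressing cells, a 3743-fold difference (log2 fold change 11.87, SE 0.21, adjusted p = 7.4e-09). The counts were 81, 57 and 74 in the controls against 212102, 299348 and 235864. CYP24A1 (ENSG00000019186) lies on the minus strand of chromosome 20 from 54153446 to 54173986 in GRCh38, by the GENCODE 44 annotation. No entry named for lncBCAS1-4_1 or BCAS1 was analysed here, so the overexpressed RNA itself was not measured. Among neighbours on the same chromosome arm, PFDN4 had a log2 fold change of -0.11 (adjusted p = 0.31), and the zinc finger gene ZNF217 fell by 0.30 on the log2 scale (adjusted p = 0.0021), although its value after the GC and length correction described next was -0.0036.

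**Figure D1:**
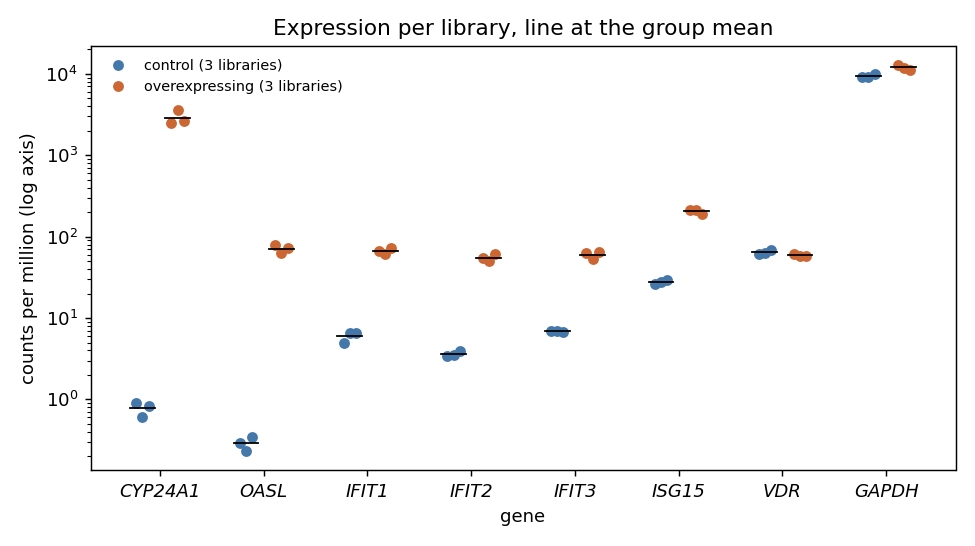
CPM (log axis) of 8 genes in each library, with 3 control and 3 overexpressing libraries as points and a line at each group mean. CYP24A1 goes from 0.778 to 2908 CPM on average and OASL from 0.290 to 71.2 CPM, while GAPDH moves from 9428 to 11989 CPM.

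Across 19101 tested entries, 3496 were higher and 3754 lower in the overexpressing cells at an adjusted p under 0.05, and 76.2% of these differences were under 1.5-fold. By the study's own criterion, more than 2-fold with an unadjusted p under 0.05, 338 were higher and 226 lower. The fold changes followed the GC content of the transcripts. Over 10128 genes with a mean log2 CPM above 3, the Spearman correlation across genes, which are not independent replicates, was 0.72. With these genes in 4 equal bins of GC content, 70.2% of genes in the lowest bin were lower and 2.8% higher, and in the highest bin 64.5% were higher and 2.1% lower. After a correction for GC content and transcript length in each library, chosen after seeing the data, 2203 genes were higher and 2118 lower, and 2824 of the 7250 calls kept their direction and their side of the threshold. The corrected values are given beside the gene groups for this reason.

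**Figure D2:**
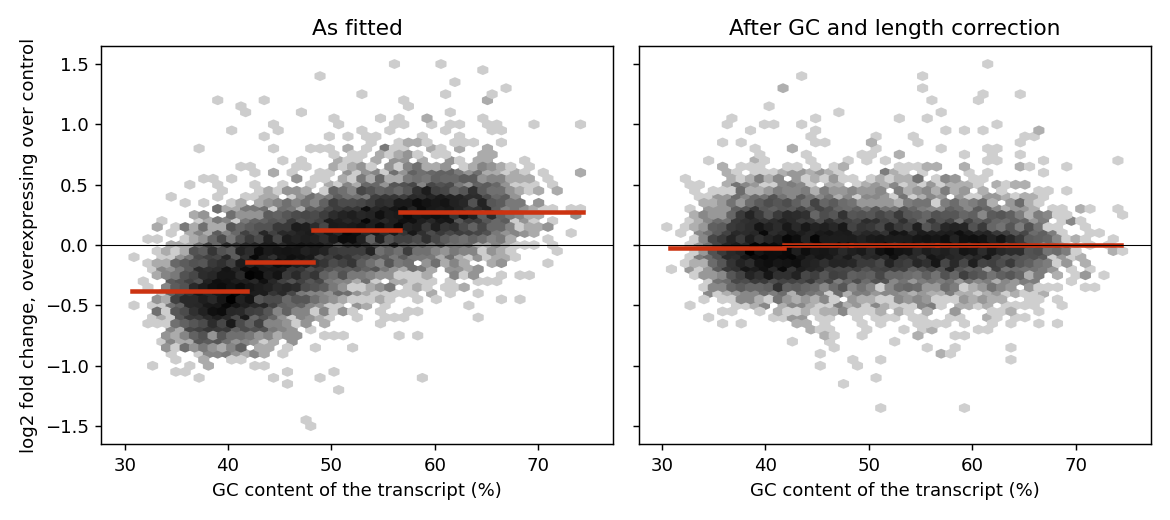
Log2 fold change (overexpressing over control) against GC content of the transcript in percent for genes with a mean log2 CPM above 3, as fitted and after the correction. Darker hexagons hold more genes, genes beyond 1.5 on either side are not drawn, and red lines mark the median of each of 4 equal bins of GC content, from -0.38 to 0.27 as fitted and from -0.021 to 0.0033 after the correction.

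Interferon-stimulated genes rose together. Of 18 measured members of the list, 17 were higher, none was lower, and the median log2 fold change was 2.54. OASL, an oligoadenylate synthetase-like antiviral protein, went from 0.290 ± 0.056 to 71.2 ± 7.3 CPM (SD, n = 3 each), a 245-fold rise. IFIT2, IFIT1 and IFIT3, which bind viral RNA or assemble with proteins that do, rose 15.1-fold, 11.2-fold and 8.77-fold, and the ubiquitin-like modifier ISG15 rose 7.33-fold from 27.9 ± 1.6 to 205 ± 15 CPM. The RNA sensor RIGI rose by a log2 fold change of 2.21 (adjusted p = 2.8e-06), and IRF9, the DNA-binding subunit of the interferon-activated transcription factor complex, by 2.94 (SE 0.39). CXCL10 had no count in any control and 105, 55 and 100 counts in the overexpressing libraries, at least 92.0-fold higher against a floor of 3 counts over the control group. With CXCL10 at that bound the list median stayed at 2.54. BST2 had a log2 fold change of 2.06 that did not pass (adjusted p = 0.098). Adjusted over the list alone, 18 were higher. The list stood above other genes by camera (adjusted p = 7.9e-14) and with an estimated correlation (adjusted p = 0.037). After the GC and length correction 16 were higher, with a median of 2.53.

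Targets of NF-kappaB, cytokines and chemokines also rose, with 13 of 17 measured members higher and 1 lower (13 rises became 14 adjusted over the list alone). The transcription factor subunit RELB rose 2.07-fold and the chemokine CXCL2 2.00-fold, from 101 ± 5 to 202 ± 8 CPM (SD, n = 3 each). The superoxide dismutase SOD2 was the lower member, at a log2 fold change of -0.33, and after the correction it was higher at 0.16 (adjusted p = 0.025). The camera call (adjusted p = 1.8e-05) was lost with an estimated correlation (adjusted p = 0.068). The estimate was -0.0018, below the preset of 0.01, so a higher correlation among the members was not what removed the call. Corrected, 11 were higher and none lower.

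Genes of glucose uptake and glycolysis showed small differences. Of 22 measured members, 11 were higher and 1 lower, with a median log2 fold change of 0.20 (11 higher and 3 lower adjusted over the list alone). GAPDH, which oxidises glyceraldehyde 3-phosphate, rose from 9428 ± 406 to 11989 ± 750 CPM (SD, n = 3 each; log2 fold change 0.35, SE 0.05, adjusted p = 0.0010). The phosphofructokinase PFKP rose by 0.29, the enolase ENO3 by 0.97 and the glucose transporter SLC2A1 by 0.29 on the log2 scale, and the lactate transporter SLC16A1 fell by 0.27. After the GC and length correction 4 members were higher and 2 lower, the median was 0.036, and GAPDH (0.059), PFKP (0.033), SLC2A1 (0.15) and SLC16A1 (0.022) no longer passed. The camera call (adjusted p = 0.016) was lost with an estimated correlation (adjusted p = 0.60) and after the correction (adjusted p = 0.16).

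The table also held 8 entries in which the gene symbol and the Ensembl ID name different genes, and these were kept out of every list. The symbols were HK2, LDHA, PKM, ENO1, VIM, CDH2, SNAI1 and TWIST1, all of them glycolysis or epithelial-mesenchymal transition genes, and GENCODE 44 gives their Ensembl IDs to C3, LMNTD2, DNAAF1, DHRS2, CES3, IFI44L, SCN3A and IFI44, in that order. They were the last 8 entries of the table, while all the others stood in the order of their Ensembl IDs. The entry with the symbol TWIST1 and the ID of IFI44, an interferon-stimulated gene, went from 0.205 ± 0.027 to 11.5 ± 0.4 CPM (SD, n = 3 each; log2 fold change 5.81, SE 0.16). The entry with the symbol CDH2 and the ID of IFI44L went from 0.044 to 0.268 CPM (log2 fold change 2.57, SE 0.74, adjusted p = 0.021), and that with the symbol SNAI1 and the ID of SCN3A had no control count and 52, 16 and 48 counts in the overexpressing libraries, at least 41.0-fold higher against the same floor. The entries with the symbols ENO1 (ID of DHRS2) and VIM (ID of CES3) rose by 1.76 and 1.23 on the log2 scale, and those with the symbols HK2 (ID of C3) and PKM (ID of DNAAF1) by 2.70 and 1.77, with adjusted p of 0.042 and 0.044 that became 0.072 and 0.096 after the correction. The entry with the symbol LDHA (ID of LMNTD2) had a log2 fold change of 1.02 and did not pass (adjusted p = 0.067). Control levels of these 8 entries were at most 1.27 CPM. Entries under the Ensembl IDs that GENCODE gives to the 8 symbols were not analysed here, so no value is given for HK2, LDHA, PKM, ENO1, VIM, CDH2, SNAI1 or TWIST1 as genes.

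Mesenchymal and epithelial genes moved in both directions. Of 22 measured mesenchymal genes 2 were higher and 4 lower, with the same counts adjusted over the list alone. The matrix protein TGFBI rose 1.88-fold and the growth factor TGFB1 1.20-fold. The transcription factors ZEB1 and ZEB2 fell by 0.61 and 0.46 on the log2 scale. SNAI2 had a log2 fold change of 0.98 (adjusted p = 0.25). After the correction TGFBI (0.74) still passed, and TGFB1 (-0.034), ZEB1 (-0.17) and ZEB2 (0.058) did not. Of 17 measured epithelial genes 4 were higher and 3 lower, again with the same counts adjusted over the list alone. The keratins KRT18, KRT7 and KRT8 rose 1.36-fold, 1.83-fold and 1.21-fold, and the junction genes TJP1, DSP and OCLN fell by 0.42, 0.51 and 0.33 on the log2 scale. Corrected, KRT7 (0.52), TJP1 (-0.14) and DSP (-0.27) still passed, and KRT18 (0.13), KRT8 (-0.035) and OCLN (0.11) did not. Neither list stood apart from other genes by camera (adjusted p = 0.83 and 0.38), and CDH1 was not analysed here.

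Vitamin D genes other than CYP24A1 moved in both directions. Of 18 measured members 7, CYP24A1 among them, were higher and 3 lower, with the same counts adjusted over the list alone and a median log2 fold change of 0.13. Without CYP24A1 6 of 17 were higher and 3 lower. Among these, 2 genes low in the controls rose most: the monocyte co-receptor gene CD14 went from 0.109 ± 0.058 to 1.28 ± 0.52 CPM (SD, n = 3 each; 11.6-fold, adjusted p = 0.00075) and the sterol hydroxylase CYP27A1 from 0.069 ± 0.032 to 0.430 ± 0.173 CPM (6.13-fold, adjusted p = 0.0069). The cell cycle inhibitor CDKN1A rose 1.77-fold and the receptor partner RXRB 1.29-fold, while G0S2 fell by 0.58, SPP1 by 0.70 and the calcium pump gene ATP2B1 by 0.44 on the log2 scale. The vitamin D receptor VDR was at 64.3 ± 4.5 CPM in the controls and 58.8 ± 2.7 CPM in the overexpressing cells (SD, n = 3 each; log2 fold change -0.13, adjusted p = 0.13). Corrected values were 3.17 for CD14, 2.31 for CYP27A1, 0.55 for CDKN1A, -0.90 for G0S2 and -0.53 for SPP1, which passed, and 0.11 for RXRB and 0.041 for ATP2B1, which did not. VDR passed as lower after the correction (log2 fold change -0.22, SE 0.05, adjusted p = 0.016). The list with CYP24A1 lay just beyond the threshold by camera (adjusted p = 0.054; adjusted p = 0.38 with an estimated correlation), and without it the adjusted p was 0.17, an alternative chosen after seeing the data.

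Messenger RNAs of the mitochondrial genome, a list that can also reflect RNA quality, fell. Whether RNA quality differed between the groups was not tested. All 13 were lower, with the same count adjusted over the list alone and a median log2 fold change of -0.70 (-0.64 after the correction, with 13 lower). MT-CO3, a cytochrome c oxidase subunit, went from 1817 ± 124 to 1097 ± 31 CPM and MT-ND6 of complex I from 220 ± 6 to 137 ± 6 CPM (SD, n = 3 each). The camera call (adjusted p = 2.4e-08) was lost with an estimated correlation (adjusted p = 0.38). Nuclear genes of the respiratory chain went mostly the other way, with 15 of 28 higher and 2 lower, both over all genes and adjusted over the list alone (11 and 1 after the correction). Only 7 of the 15 higher as fitted were still higher after the correction. COX5B rose 1.37-fold and NDUFA4 1.25-fold. By camera the adjusted p was 0.0067, and 0.63 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 24 of 32 cases and lower in 1 (25 and 1 adjusted over the list alone), with RPS2 at 1.34-fold and RPS9 at 1.33-fold. After the correction 14 were higher and 3 lower, and neither RPS2 (0.076) nor RPS9 (0.067) passed. Only 10 of the 24 higher as fitted were among these 14. The camera adjusted p was 3.9e-06, and 0.60 with an estimated correlation.

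Genes of S and G2/M phase were lower in 15 of 30 cases and higher in 4 (18 and 4 adjusted over the list alone). The proliferation marker MKI67 fell by 0.70 on the log2 scale, from 521 ± 35 to 321 ± 10 CPM (SD, n = 3 each), and the topoisomerase TOP2A by 0.81. The replicative helicase genes MCM7 and MCM2 rose 1.21-fold and 1.18-fold. After the correction 18 were lower and none higher, with MKI67 at -0.45 and TOP2A at -0.39, and MCM7 (0.042) and MCM2 (0.028) no longer passed. Only 9 of the 15 lower as fitted were among these 18. By camera the adjusted p was 0.013, and 0.63 with an estimated correlation.

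Unfolded protein and integrated stress response genes rose in 17 of 20 cases with none lower (18 higher and 1 lower adjusted over the list alone; 16 higher after the correction). CHAC1, which degrades glutathione, rose 3.56-fold and the transcription factor ATF3 3.55-fold. The camera adjusted p was 2.4e-08, and 0.25 with an estimated correlation. Cholesterol synthesis and uptake genes rose in 16 of 19 cases with 1 lower, the same counts as adjusted over the list alone (17 higher and none lower after the correction). MVD rose 1.97-fold and the lanosterol synthase LSS 1.56-fold, and the sterol carrier STARD4 fell by 0.40 on the log2 scale but not after the correction (0.024). The camera adjusted p was 4.2e-07, and with an estimated correlation 0.055 as fitted and 0.015 after the correction. The estimate as fitted was -0.050, again below the preset. Immediate early genes, which also respond to handling, rose in 13 of 16 cases with 1 lower, likewise adjusted over the list alone (10 and 1 after the correction), among them FOSB at 4.64-fold, EGR1 at 3.74-fold, the nuclear receptor NR4A1 at 2.79-fold and JUNB at 1.98-fold, while KLF6 fell by 0.24 on the log2 scale. Tested by camera, the list had an adjusted p of 1.0e-06, and 0.25 with an estimated correlation. Genes induced by TGF-beta rose in 9 of 15 cases with 1 lower (10 and 2 adjusted over the list alone; 8 and 2 after the correction), among them ID1 at 1.70-fold. Tested by camera, they had an adjusted p of 0.00086, and 0.25 with an estimated correlation. Replication-dependent histone genes, whose RNAs lack poly(A) tails, also mark how the RNA was selected. They rose in 5 of 14 cases with none lower (6 higher adjusted over the list alone), H2BC12 by 1.52-fold. Their camera adjusted p of 0.0075 became 0.22 with an estimated correlation, itself -0.066 and below the preset, and 0.44 after the correction.

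**Figure D3:**
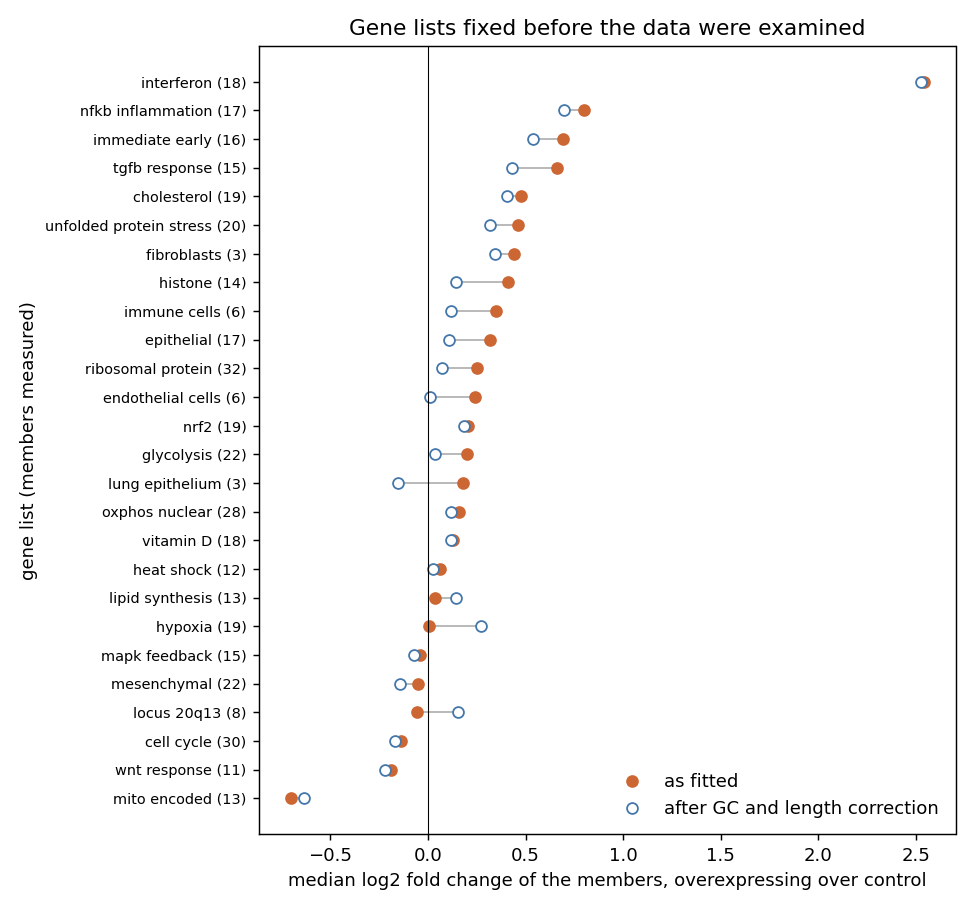
Median log2 fold change (overexpressing over control) of the measured members of 26 gene lists, as fitted (filled points) and after the GC and length correction (open points). The interferon list sits at 2.54 and 2.53, the mitochondrially encoded genes at -0.70 and -0.64, and the glycolysis list at 0.20 and 0.036.

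The remaining lists did not stand apart from other genes by camera as fitted. After the correction the NRF2, fatty acid synthesis and hypoxia lists did (adjusted p = 0.0036, 0.0036 and 0.0062), but not with an estimated correlation (adjusted p = 0.32, 0.31 and 0.38). The NRF2 list had 7 of 19 higher and 2 lower (adjusted p = 0.13), with OSGIN1 2.27-fold up. Hypoxia genes had 5 of 19 higher and 3 lower (adjusted p = 0.61), with BHLHE40 up 1.89-fold and BNIP3 down by 0.47 on the log2 scale. Heat shock genes had 4 of 12 higher and 3 lower (adjusted p = 0.56), with HSPA1A up 1.76-fold and HSP90AA1 down by 0.62. Fatty acid synthesis genes had 6 of 13 higher and 5 lower (adjusted p = 0.67), with SCD up 1.36-fold. ERK feedback genes had 2 of 15 higher and 4 lower (adjusted p = 0.61), Wnt targets 3 of 11 higher and 2 lower (adjusted p = 0.83), and the list of CYP24A1 and genes around it on its chromosome arm 2 of 8 higher, CYP24A1 and BCAS4, and 2 lower (adjusted p = 0.83). Without CYP24A1, 1 of 7 was higher and 2 were lower (adjusted p = 0.58). MYC, in both the ERK and Wnt lists, rose 1.20-fold, and CCND1 fell by 0.23 on the log2 scale. Markers of other cell types were higher in 2 of 6 cases for immune cells (CD68 and CSF1R), 1 of 6 for endothelium (EGFL7), 0 of 3 for fibroblasts and 1 of 3 for differentiated lung epithelium (FOXJ1), with none lower and with none past the threshold after the correction.

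Among genes with a mean log2 CPM of at least 2, the other large rises were those of DMBT1, a secreted scavenger receptor protein, at 17.9-fold, and of the nuclear receptor NR4A2 at 5.38-fold. The largest falls were smaller. KRTAP2-3, a keratin-associated protein gene with near-identical copies, fell by 1.70 on the log2 scale, ZNF891 by 1.55, the DNA demethylase TET1 by 1.22, the pseudogene ZNF702P by 1.18 and AOX1 by 1.17. The spindle gene ASPM fell by 1.09, and GLIS3, PTPRZ1, NAV3 and EML5 each by 1.08. After the correction all but EML5 (-0.62, adjusted p = 0.080) still passed, with ASPM at -0.53 and ZNF891 at -0.99 (ZNF702P had no annotated GC content and was left as fitted). Values of KRTAP2-3, HSPA1A, HSPA1B, ZNF702P, GAPDH, the ribosomal protein genes and the mitochondrial genes are uncertain to the extent that reads were shared with near-identical copies, and those of genes with antisense or overlapping partners because the strand setting is not stated.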

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

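The GC and length correction, the readings of the 8 entries of disagreeing identity and the lists without CYP24A1 were chosen after seeing the data, and the other alternatives before. Of the 107 named genes, 106 kept their direction and side of the threshold with DESeq2 size factors, 103 with library size alone, 106 with limma-voom, 96 with the replicate block (10 no longer passed) and 69 with the correction, which left 22 no longer past the threshold, turned 15 in sign and brought 1, VDR, past it (-0.22). With single libraries left out 96 to 102 kept both and 5 to 11 no longer passed, most without control 2. The entry with the symbol LDHA and the ID of LMNTD2 passed under DESeq2 (LDHA adjusted p = 0.033), limma-voom (0.038), the block (0.037) and without control 3 (0.0065), and VDR with library size alone (0.032). Library size alone gave 2908 higher and 4274 lower, and scaling shifted the median log2 fold change by at most 0.05. The filter of 10 counts in 3 libraries removed no entry. A 2-fold filter, which can only lower the counts, left 255 higher and 148 lower. With the correction 2203 genes were higher and 2118 lower, of which 1497 had not been called in that direction before; the cause was not tested. Signs turned for SLC16A1 (0.022), TGFB1 (-0.034), ZEB2 (0.058), KRT8 (-0.035), OCLN (0.106), ATP2B1 (0.041), ERO1A (0.074), ATP5PB (0.036), CYCS (0.123), RPS6 (0.010), SOD2 (0.163), STARD4 (0.024), ACSL3 (0.093), EPHA2 (-0.073) and CD68 (-0.058), of which SOD2 alone passed afterwards. The glycolysis list lost its call with the correction (adjusted p = 0.160) and with an estimated correlation (adjusted p = 0.60); taking the 8 entries by symbol gave 14 of 26 higher and an adjusted p of 0.0020, and 0.41 with an estimated correlation. By symbol and with the correction, 5 were higher and 2 lower and the list kept its camera call (adjusted p = 0.019). The mesenchymal list stayed beyond the threshold by symbol (0.42), and the interferon list with the entries taken by Ensembl ID had 19 of 20 higher. The vitamin D list, CYP24A1 included, passed by camera under the DESeq2 statistics (1.1e-05) and the replicate block (0.0385); the cause was not tested. Without CYP24A1 its adjusted p was 0.168. By fry, which asks whether the set moves one way on balance and compares it with no other genes, its adjusted p was 0.0011. Leaving out each library gave it adjusted p from 0.0352 to 0.119, passing without control 3 (0.0422) and without overexpressing library 3 (0.0352). Every list that lost its camera call with an estimated correlation passed by fry as fitted. Adjusted p by fry was 0.029 for glycolysis, 0.0011 for mitochondrial, 0.020 for ribosomal protein, 0.014 for cell cycle and 1.3e-05 for histone genes. Fry also passed lists that camera did not, such as heat shock (0.029), and was not run with the correction. Leave-one-out counts ran from 2591 to 3446 higher and from 2869 to 3740 lower, and the glycolysis list from 0.0063 to 0.043. Replicate numbers did not pair the samples: same-numbered libraries correlated at -0.039, -0.27 and -0.29 in their deviations from the group means, and the block gave 2681 higher and 3014 lower. At 84531039 to 92780032 counts per library, entries under 0.1 CPM in the controls rest on only a few counts.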

Other observations

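The gene families and the tests below were chosen after the data were seen, apart from the counts over other splits of the libraries. Chemokine genes of the CXCL and CCL families rose in 8 of 13 measured cases with none lower. After the GC and length correction 8 were higher, without CXCL16 (adjusted p = 0.15) and with CXCL5 (adjusted p = 0.049). CXCL3 went from 0.966 ± 0.193 to 2.17 ± 0.15 CPM and CXCL1 from 1.34 ± 0.38 to 2.35 ± 0.15 CPM (SD, n = 3 each). CCL5 had 0, 0 and 4 counts in the controls and 140, 115 and 94 in the overexpressing libraries. All 3 nuclear receptors of the NR4A family rose, with NR4A3 at a log2 fold change of 3.22 (3.38 corrected). Of 11 entries with HLA symbols 5 were higher, and 2 after the correction, HLA-C (0.27) and HLA-E (0.32). These entries include the pseudogene HLA-H and the non-coding HLA-F-AS1 and HLA-L. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 had log2 fold changes of -0.072 and -0.14 that did not pass, beside the fall of all 13 mitochondrial messenger RNAs. Of 22 mitochondrial tRNAs 9 were lower and 3 higher, and 5 and 5 after the correction. Of 543 entries with ZNF symbols, 155 were lower and 42 higher, and 58 and 24 after the correction. These were taken by symbol and include antisense RNAs, divergent transcripts and pseudogenes beside the zinc finger genes.

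The counts of changed genes were set against other splits of the 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many calls in each case: 3496 higher against 2 at most elsewhere, 3754 lower against 2, and 564 by the study's criterion against 145.

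The trend of fold changes with GC content was found in these data. A single library carrying it is argued against, since the correlation was at least 0.696 with any library left out, and so is transcript length standing behind it, since the partial correlation given length was 0.69. Other splits of the libraries also gave trends, beside the correlation of 0.72 for the groups. Correlations were 0.78 for controls 1 and 2 with overexpressing library 3 against the rest, and 0.71 with overexpressing library 1 in its place. Both splits still set 2 controls against 2 overexpressing libraries, so part of the group contrast stayed in them. A rank correlation also does not measure the size of a trend. These correlations therefore do not show whether the trend is particular to the group contrast. The trend may account for many of the small differences: 39.0% of the called genes stayed past the threshold in the same direction after the correction. It did not account for the larger ones as a set, of which 64.9%, or 366 of 564, still met the study's criterion. Whether the trend came from library preparation or from the cells cannot be told apart, because every overexpressing library had a higher slope of log2 CPM on GC content than every control (a gap of 0.14 log2 per 10 percentage points between the nearest libraries) and no label gives a batch.

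The 8 entries with a symbol and an Ensembl ID of different genes would, by symbol, add rises in genes of the study's themes. By level, the entry with the symbol PKM, the pyruvate kinase of most dividing cells, was at 0.118 CPM in the controls, against 673 CPM for phosphofructokinase, the lowest of the other glycolytic steps that involve none of the 8 symbols; PKLR was not analysed here, so this does not exclude the symbol. The highest control level among the other 7 was 1.27 CPM. With the entries of the symbols HK2, ENO1 and LDHA included, the controls summed to 112 CPM for hexokinase, 58.2 for enolase and 1342 for lactate dehydrogenase. Other entries of the same step carried nearly all of each sum. The enolase and hexokinase sums also lay below the 673 CPM of phosphofructokinase, and the lactate dehydrogenase sum lay above it. No level was set for the 7 genes one by one. Low as these entries are, their levels therefore do not exclude the symbols. The entries with the IDs of IFI44 and IFI44L rose, the lower of them by 2.57 on the log2 scale, as other interferon-stimulated genes did. Of the 8 entries 7 passed as higher, among them those with the IDs of SCN3A, CES3 and DHRS2, which are not on the interferon list. A rise past the threshold therefore cannot tell the ID from the symbol. The IFI44L entry also rested on 4, 4 and 4 control counts against 10, 21 and 39. The other 6 IDs were not tested, and the reads would be needed to settle any of the 8.

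The rise of CYP24A1 was weighed against 4 explanations. The GC and length trend is argued against by the corrected log2 fold change of 11.95. A joint activation of the locus list is argued against by the median of -0.11 over its other measured genes. Some of these lie far from CYP24A1 (start 54153446), such as BCAS4 (start 50794894) and AURKA (start 56369389), and BCAS1 was not analysed here. A rise limited to the genes nearest to CYP24A1 is therefore not excluded. Activation of the vitamin D receptor stays open, since the other vitamin D genes went both ways around a median of 0.13, with CD14 and CYP27A1 higher and G0S2 and SPP1 lower. Reads of the overexpressed RNA counted on CYP24A1 may also be a source and stay open, since 0 entries were named for that RNA and no reads were analysed here. An effect of the overexpressed RNA on the cells' own CYP24A1 gene, which the design names, was not tested apart from these.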
